A study of Mus musculus with 156 samples.

How the data were processed

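RNA from whole blood, spleen and subcutaneous tumour was sequenced from BALB/c mice with A20 lymphoma and C57BL/6 mice with B16F10 melanoma, in 156 polyA libraries prepared by standard Illumina methods. Mice received 1 intravenous dose of TAK-981 at 2.5, 5, 7.5 or 15 mg/kg or the 20% HPbCD vehicle at a tumour volume of about 500 mm3, and tissue was collected after 4 h or 8 h. Spleen was collected after vehicle, 7.5 and 15 mg/kg. Each of the 52 groups held 3 mice.

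The deposited files gave expected counts per gene as the authors estimated them from the reads, not scaled for depth, per the file headers. Of the non-zero values 28.43% were not whole numbers. The deposited FPKM values had been scaled by the authors to gene length and library total. The aligner, the counting program and the genome build are not given in the sources used here. Values were listed for 43432 gene identifiers, of which 42462 were matched to a symbol in GENCODE M21, 970 had none and 40 shared one. Total counts per library ranged from 35971181 to 62727556. At this depth the limit on precision was the spread between 3 mice rather than the counts. In data simulated with the fitted dispersions a log2 change of 2 was called for 42.4 to 81.8% of 66 genes and a change of 1 for 1.49 to 46.3% of 67, with at most 0.0390% false calls. A simulation with the dispersion divided by 10 was added after that result was seen and called 89.4 to 98.5%.

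Libraries were grouped by strain, tissue, dose and hour as the labels give them, in 6 sets (BALB/c blood and spleen, A20 tumour, C57BL/6 blood and spleen, B16F10 tumour). Counts were rounded, scaled by TMM and filtered with filterByExpr in edgeR 4.0.16 under R 4.3.3. Each set was fitted with 1 coefficient per group, so that all groups shared the estimate of spread, and contrasts were tested by edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. A gene past the threshold is said to be called, risen or fallen. Log2 changes are printed with their standard errors, and CPM values with standard deviations over 3 mice. There were 40 comparisons of a dose with vehicle, 6 differences between the 8 h and 4 h effects of 15 mg/kg within a set and 6 differences between the 2 models within a tissue and hour. The counts of genes for 20 dose steps (15 against 7.5 and 5 against 2.5 mg/kg) were added after the data were seen. DESeq2 1.42.0 was run beside edgeR. Tables were handled with the packages data.table (1.17.8) and jsonlite (2.0.0).

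Gene lists (29) were written from general knowledge and covered type I interferon response (58 genes, 57 in the files), interferon gamma response, interferon ligands, MHC class I and class II presentation, NF-kB and inflammatory cytokines, costimulation and dendritic cell maturation, lymphocyte activation and checkpoints, SUMO pathway, p53 targets, heat shock and unfolded protein response, immediate early genes, glucocorticoid response, circadian clock, cell cycle, germline and early embryo genes, and markers of T, NK, B and plasma cells, neutrophils, monocytes and macrophages, dendritic cells, erythroid cells, platelets and megakaryocytes, melanocytes, fibroblasts, endothelium, and keratinocyte, muscle and fat. Symbols without a match were Mnda, Gbp5, Gbp6, H2-L, Hbb-b1 and Hbb-b2. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The value of a list is the median log2 fold change of its members. Camera with an estimated correlation and fry, which asks whether a list moves on balance one way without comparing it with other genes, were run beside it. With the estimated correlation most list calls were lost, and the adjusted p is printed where that happened. Counts adjusted over the list alone use the Benjamini-Hochberg adjustment over the members only. The interferon list was also compared in the 20 dose steps and in 8 differences between tissues.

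The interferon score of a library is the mean over the type I interferon list of log2 CPM minus the mean of the vehicle group of the same set and hour. Its relation to dose was tested over the 12 treated libraries of a set and hour by two-sided permutation tests (100000 permutations, smallest p 1e-05) for Spearman's rho and Pearson's r, adjusted over the 8 relations. Within a range of library identifiers, 6 libraries each, all splits of 3 against 3 were enumerated, which gives a smallest exact p of 0.1.

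Genes were named by a rule written with the lists. It takes the 5 largest rises and 5 largest falls of each comparison of 15 mg/kg with vehicle among called genes with a mean CPM of at least 5 in the higher group and every treated library beyond every vehicle library. It adds a panel of 12 genes in any comparison (among them Isg15, Ifit1, Ifit3, Mx1, Oasl2, Rsad2, Irf7, Usp18, Cxcl10, Ifnb1, Cd274), up to 4 called members of each list by smallest p, and the 2 largest differences per direction between times and models. The SUMO enzyme genes Sae1 and Uba2, among others, may be named in any comparison. Library features outside the rule (Alb, Xist, Gm42418, Hbb-bs, Cd3e, S100a8, the 18 liver markers, the 22 genes called alike in both tumours and the dose values of Sumo3) were chosen after their values were seen.

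Each result was recomputed with RLE size factors, without the low-count filter, with DESeq2, with only the compared groups in the fit, without haemoglobin and immunoglobulin genes, with the replicate number as a block and with each library of the compared groups left out in turn. List and score results were also recomputed with log2(FPKM + 0.1) and a prior count of 0.5, list results with RLE size factors, fry and an estimated correlation, tissue differences with the group and replicate number taken as a mouse block, and the score with the vehicle libraries included and with log2 of the dose. Leaving out 5 libraries that stand apart, adding log2 Alb CPM as a covariate in blood, and the interferon list's time and model differences in these alternatives were added after the data were seen. Where a group was left with 2 libraries the fit pooled the spread of all groups. Every 3 against 3 comparison was repeated over the 10 splits of its libraries, and differences of effects over 100 of 200 relabellings. Splicing, variants and reads as sequenced were not analysed here. No library was left out of the values reported unless stated.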

Results

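TAK-981, an inhibitor of the SUMO-activating enzyme, was given once by vein to BALB/c mice bearing A20 B-cell lymphomas and to C57BL/6 mice bearing B16F10 melanomas. The question named for the series is whether the compound switches on type I interferon signalling. Whole blood, spleen and tumour were taken at 4 h and 8 h after 2.5, 5, 7.5 or 15 mg/kg or the 20% HPbCD vehicle, with spleen taken at 7.5 and 15 mg/kg only. There were 3 mice per group, 52 groups and 156 polyA RNA libraries, which held 35971181 to 62727556 counts each. Each dose was compared with the vehicle of its hour by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. Gene lists fixed before the data were examined were tested with limma's camera. The library identifiers fall in 3 ranges, vehicle, 2.5 with 5 mg/kg, and 7.5 with 15 mg/kg. Each comparison with vehicle is therefore also a comparison between ranges. Values within a range are given where the design holds them.

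Interferon-response genes rose in the blood of A20-bearing BALB/c mice within 4 h of 15 mg/kg, and B-cell transcripts were depleted by 8 h. Of the 57 measured genes of the type I interferon response list, 55 rose at 4 h (56 adjusted over the list alone, median log2 change 2.93, adjusted p = 3.4e-128) and 56 at 8 h (56 adjusted over the list alone, median 2.88). Ifit3, an antiviral effector, rose by log2 5.75 ± 0.52 at 4 h (adjusted p = 5.8e-08) and Usp18, the ISG15 protease, by 5.00 ± 0.38 to 516 ± 18.9 CPM against 16.1 ± 3.94 in vehicle. The chemokine Cxcl10 (5.40 ± 0.68), Mx1 (4.94 ± 0.46) and the checkpoint ligand Cd274 (2.68 ± 0.26) rose with them, each with an adjusted p of at most 5.8e-06. Interferon beta (Ifnb1) itself was counted at 0.535 ± 0.760 CPM at 8 h (42 counts against 0 in vehicle, adjusted p = 0.0379). That call ended without any 1 of the vehicle libraries, without treated replicate 1 or 2, and with albumin (Alb) as a covariate. MHC class I presentation genes rose at both hours (19 of 20 higher, 20 adjusted over the list alone, median 1.54, adjusted p = 1.3e-45 at 4 h and 18 of 20 higher, 19 adjusted over the list alone, median 1.07, adjusted p = 2.5e-18 at 8 h). Their member H2-T22 had 2.32 ± 0.19 and 1.87 ± 0.18.

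The same blood lost B-cell and MHC class II transcripts. B cell markers fell already at 4 h (7 of 15 lower, 11 adjusted over the list alone, median -0.89, adjusted p = 4.2e-09, adjusted p = 0.291 with an estimated correlation), and at 8 h all 15 were lower (15 adjusted over the list alone, median -3.08, adjusted p = 2.5e-19). The IgE receptor Fcer2a changed by -5.74 ± 0.55 to 2.27 ± 1.35 CPM and the complement receptor Cr2 by -5.15 ± 0.48. MHC class II presentation genes followed at 8 h (9 of 10 lower, 9 adjusted over the list alone, median -2.26, adjusted p = 1.8e-08, adjusted p = 0.166 with an estimated correlation), with H2-Aa at -2.50 ± 0.32. T cell markers were lower too (9 of 19 lower, 9 adjusted over the list alone, median -0.72, adjusted p = 4.8e-04, adjusted p = 0.424 with an estimated correlation). Neutrophil markers rose (11 of 18 higher, 12 adjusted over the list alone, median 1.62, adjusted p = 1.3e-07, adjusted p = 0.166 with an estimated correlation), among them Ly6g (2.90 ± 0.45) and Stfa2l1 (3.24 ± 0.44). Heat shock and unfolded protein response genes rose (14 of 24 higher, 14 adjusted over the list alone, median 0.77, adjusted p = 4.5e-09). The monocyte chemoattractants Ccl2 (8.52 ± 1.23) and Ccl7 (11.40 ± 1.65) were among the largest rises. Liver-enriched genes stood beside them. Cyp2c37 reached 8.26 ± 8.01 CPM (734 counts against 0 in vehicle, adjusted p = 0.0121) and Cyp4a10 7.21 ± 6.06 CPM (638 counts against 0, adjusted p = 0.0123), so no fold is given. In all, 578 genes rose and 241 fell at 4 h, 2137 and 2525 at 8 h, of 16922 tested. The 4 h count of 819 became 520 without vehicle replicate 2. With RLE size factors 2441 rose and 2089 fell at 8 h and with DESeq2 2850 and 2367, so the balance turned with the scaling. The 8 h count of 4662 became 1738 with the compared groups alone, 2275 with albumin (Alb) as a covariate, and 2774 without treated replicate 1.

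Blood of B16F10-bearing C57BL/6 mice also gained interferon-response and lost B-cell transcripts. At 15 mg/kg 49 of 57 type I interferon response genes rose at 4 h (53 adjusted over the list alone, median 2.16, adjusted p = 3.2e-39, 0.274 with an estimated correlation) and 52 at 8 h (55 adjusted over the list alone, median 2.16, adjusted p = 2.6e-24, 0.263 with an estimated correlation). At 8 h replicate 3 scored 0.546 against 2.99 and 3.12, and without it the median was 3.05. Ifit3 rose by 5.01 ± 0.80 and 5.56 ± 0.82, Cxcl10 by 6.04 ± 1.04 and 6.19 ± 1.06, and Usp18 by 3.68 ± 0.48 at 4 h (adjusted p = 1.3e-04). Ifnb1 held 56 counts against 0 at 4 h (adjusted p = 0.0665). Tnfrsf23 rose by 5.67 ± 0.47 at 4 h (adjusted p = 1.2e-07). Neutrophil markers rose at 4 h (8 of 16 higher, 11 adjusted over the list alone, median 1.78, adjusted p = 4.0e-08, adjusted p = 0.274 with an estimated correlation), with Mxd1 at 2.02 ± 0.42. Platelet and megakaryocyte markers rose at 8 h (12 of 12 higher, 12 adjusted over the list alone, median 1.39, adjusted p = 1.5e-07, adjusted p = 0.274 with an estimated correlation), with Ppbp at 1.77 ± 0.38. B cell markers at 8 h were again all lower (15 of 15 lower, 15 adjusted over the list alone, median -2.98, adjusted p = 3.2e-16, adjusted p = 0.222 with an estimated correlation), led by Fcer2a at -5.11 ± 0.59 and Cd79b at -3.25 ± 0.34. MHC class II presentation genes fell (9 of 10 lower, 9 adjusted over the list alone, median -2.64, adjusted p = 1.3e-10, adjusted p = 0.222 with an estimated correlation), with their transactivator Ciita at -3.58 ± 0.39. Endothelial markers rose (7 of 13 higher, 8 adjusted over the list alone, median 2.06, adjusted p = 1.7e-04, adjusted p = 0.274 with an estimated correlation). The library of 15 mg/kg 8 h replicate 3 held 6.42% of its counts in liver markers and 11.5% in mitochondrial genes. It also had 0.0636 CPM of Xist, a gene chosen after its values were seen, and replicate 3 of the same dose and hour had 0.987 CPM in spleen and 0.115 CPM in the tumour. Over all genes 666 rose and 575 fell at 4 h, 2436 and 2668 at 8 h. The balance turned with RLE size factors (2921 and 2095) and DESeq2 (3394 and 2316) at 8 h, and without haemoglobin and immunoglobulin genes (626 and 732) at 4 h. The 1241 calls of 4 h became 2261 with DESeq2, 769 with no low-count filter, 2954 with the compared groups alone, 2479 without the libraries that stand apart, 300, 293 and 514 without vehicle replicates 1, 2 and 3, and 506 and 349 without treated replicates 2 and 3. The 5104 of 8 h became 327 with the compared groups alone, and 3290 without vehicle replicate 1.

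**Figure D1:**
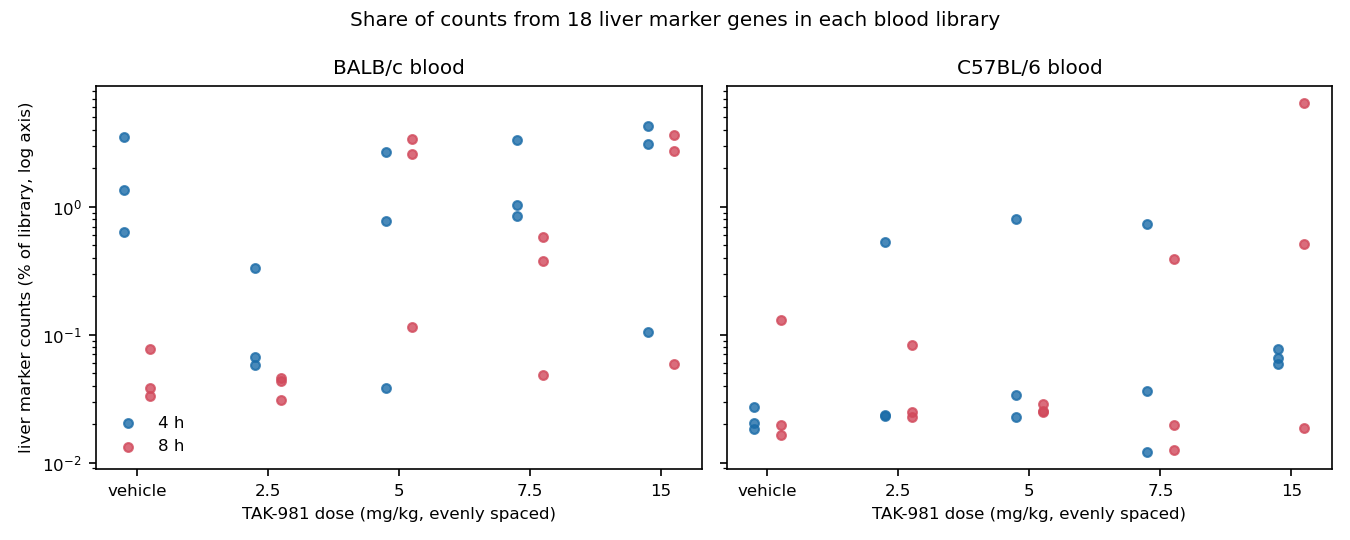
Share of counts from 18 liver marker genes (vertical axis, % of library, log scale) in each blood library by dose in mg/kg (horizontal axis, evenly spaced), points for libraries of 4 h and 8 h, 3 mice per group. The vehicle libraries of BALB/c blood already span 0.0333 to 3.48%.

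**Figure D2:**
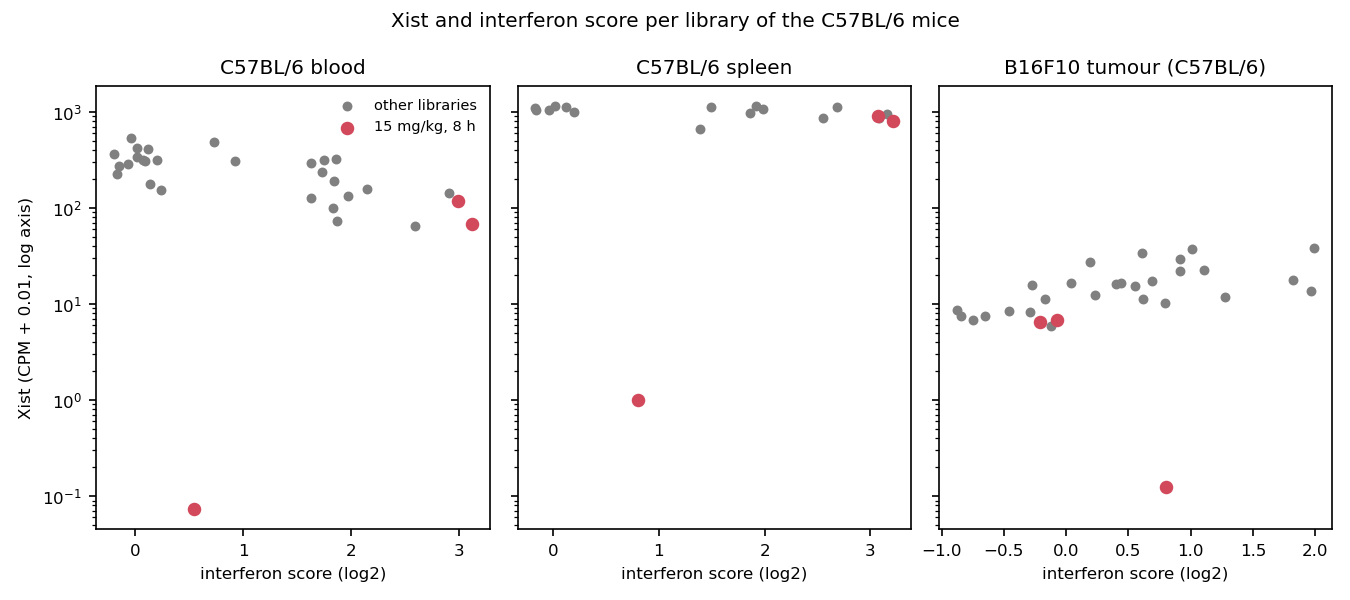
Xist (vertical axis, CPM + 0.01, log scale) against the interferon score (horizontal axis, log2) in each C57BL/6 library of blood, spleen and tumour, with 15 mg/kg 8 h in red. Replicate 3 of that group has 0.0636, 0.987 and 0.115 CPM of Xist.

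**Figure D3:**
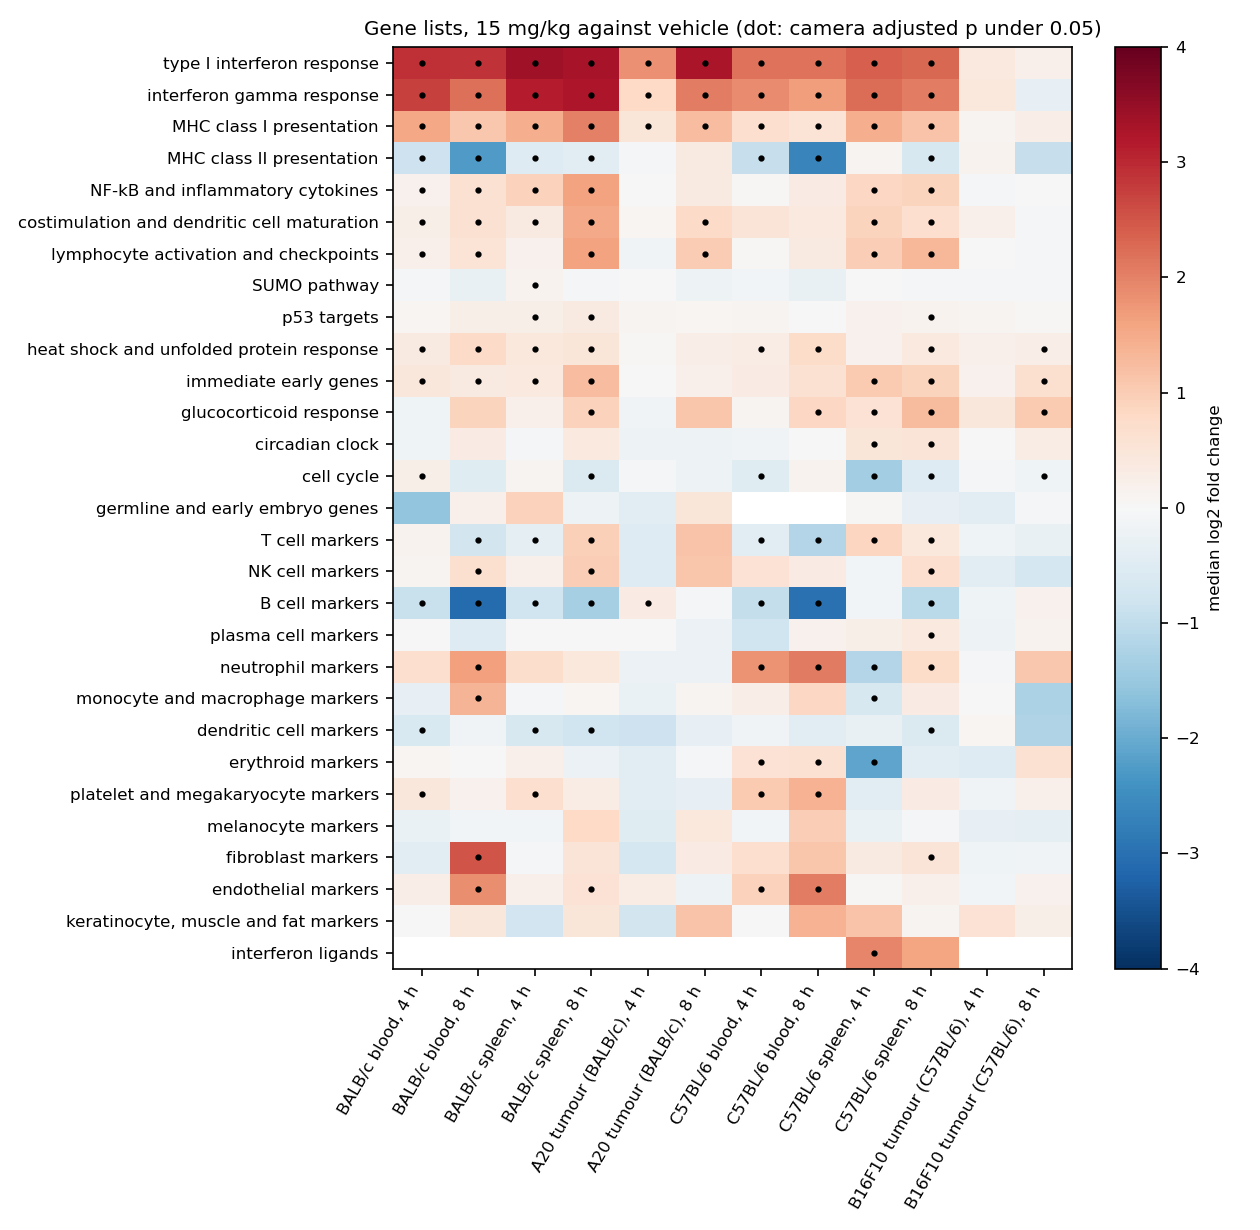
Median log2 fold change of each fixed gene list (vertical axis) at 15 mg/kg against vehicle in each tissue and hour (horizontal axis), 3 mice per group, with a dot where camera's adjusted p is under 0.05. Type I interferon response genes have medians of 2.93 in BALB/c blood and 0.39 in B16F10 tumours at 4 h.

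In the spleens of A20-bearing mice at 15 mg/kg all 57 type I interferon response genes rose at both hours (median 3.40, adjusted p = 5.5e-68, adjusted p = 0.112 with an estimated correlation at 4 h). At 8 h the values were median 3.28, adjusted p = 2.8e-53, adjusted p = 0.118 with an estimated correlation. Mx1 went from 13.6 ± 1.72 to 938 ± 86.1 CPM (log2 6.11 ± 0.39) at 4 h, and Ifit2 changed by 5.90 ± 0.36. Ifnb1 was counted here at both hours, at 4.37 ± 0.873 CPM (516 counts against 0 in vehicle, adjusted p = 1.1e-04) and 1.32 ± 0.117 CPM (158 counts against 0, adjusted p = 4.1e-04). Interferon gamma (Ifng) rose by 2.69 ± 0.36 at 4 h, and interferon gamma response genes rose at 8 h (24 of 27 higher, 25 adjusted over the list alone, median 3.24, adjusted p = 6.2e-21, adjusted p = 0.134 with an estimated correlation). NF-kB and inflammatory cytokine genes climbed by 8 h (26 of 29 higher, 27 adjusted over the list alone, median 1.60, adjusted p = 5.5e-15, adjusted p = 0.146 with an estimated correlation), including Ccl12 (8.26 ± 0.84), Ccl4 (5.51 ± 0.52) and the interleukin-1 antagonist Il1rn (3.56 ± 0.32). Lymphocyte activation genes rose (13 of 15 higher, 14 adjusted over the list alone, median 1.60, adjusted p = 7.9e-08, adjusted p = 0.262 with an estimated correlation), with Gzmb at 4.29 ± 0.51 and Lag3 at 2.50 ± 0.25. So did T cell markers (13 of 19 higher, 15 adjusted over the list alone, median 0.95, adjusted p = 1.6e-05, 0.482 with an estimated correlation) and NK cell markers (7 of 12 higher, 7 adjusted over the list alone, median 0.98, adjusted p = 0.00195, 0.455 with an estimated correlation). Costimulation and dendritic cell maturation genes rose (12 of 16 higher, 13 adjusted over the list alone, median 1.51, adjusted p = 3.8e-08, adjusted p = 0.223 with an estimated correlation). Dendritic cell markers fell (6 of 12 lower, 6 adjusted over the list alone, median -0.78, adjusted p = 0.0216, adjusted p = 0.478 with an estimated correlation), with Xcr1 at -1.78 ± 0.29 and Clec9a at -1.36 ± 0.19. Further lists that rose at 8 h were immediate early genes (14 of 19 higher, 17 adjusted over the list alone, median 1.24, adjusted p = 1.6e-09, 0.146 with an estimated correlation), glucocorticoid response genes (10 of 14 higher, 11 adjusted over the list alone, median 0.93, adjusted p = 1.4e-05, 0.118 with an estimated correlation) and p53 targets (10 of 22 higher, 11 adjusted over the list alone, median 0.37, adjusted p = 0.0112, 0.145 with an estimated correlation). Their members included Junb at 2.84 ± 0.27, Fkbp5 at 1.55 ± 0.14 and Cdkn1a at 2.14 ± 0.23. B cell markers (12 of 15 lower, 12 adjusted over the list alone, median -1.34, adjusted p = 8.2e-08, adjusted p = 0.262 with an estimated correlation) and cell cycle genes (11 of 32 lower, 15 adjusted over the list alone, median -0.58, adjusted p = 3.0e-05, adjusted p = 0.614 with an estimated correlation) fell. The SUMO pathway list passed its test in this tissue at 4 h (8 of 31 higher, 8 adjusted over the list alone, median 0.13, adjusted p = 0.0418, adjusted p = 0.566 with an estimated correlation). There Daxx (3.91 ± 0.34) and Pml (2.18 ± 0.16), nuclear body proteins that are also interferon-induced, had the largest rises of its members. Of 18252 genes tested, 1716 rose and 1673 fell at 4 h and 2850 and 2363 at 8 h. Without haemoglobin and immunoglobulin genes 1655 rose and 1791 fell at 4 h. The 3389 calls of 4 h became 2231 without treated replicate 3.

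Spleens of B16F10-bearing mice gained interferon-response transcripts too. Of the 57 interferon genes 51 rose at 4 h (55 adjusted over the list alone, median 2.40, adjusted p = 2.1e-26, 0.669 with an estimated correlation) and 50 at 8 h (56 adjusted over the list alone, median 2.28, adjusted p = 5.4e-34, 0.284 with an estimated correlation). At 8 h 15 mg/kg replicate 3 scored 0.802 against 3.08 and 3.21, and without it the median was 3.03. Ifit1 had 4.52 ± 0.67 and 4.40 ± 0.66. Ifnb1 reached 2.61 ± 0.897 CPM at 4 h (338 counts against 0 in vehicle, adjusted p = 0.0168, a call that ended without any 1 of the vehicle libraries). The interferon ligands list, with 3 genes measured, rose at 4 h (1 of 3 higher, 3 adjusted over the list alone, median 1.96, adjusted p = 0.0366, adjusted p = 0.669 with an estimated correlation). MHC class I presentation genes rose (13 of 20 higher, 19 adjusted over the list alone, median 1.45, adjusted p = 9.8e-10, adjusted p = 0.669 with an estimated correlation), H2-Q7 by 1.91 ± 0.34. Circadian clock genes rose at 8 h (2 of 17 higher, 6 adjusted over the list alone, median 0.51, adjusted p = 0.00103, adjusted p = 0.308 with an estimated correlation). Plasma cell markers had a median of 0.38 (adjusted p = 0.0206, 0.427 with an estimated correlation). B cell markers fell at 8 h (6 of 15 lower, 8 adjusted over the list alone, median -1.08, adjusted p = 1.6e-07, adjusted p = 0.284 with an estimated correlation), and Fcer2a went from 170 ± 44.2 to 13.5 ± 3.35 CPM (-3.66 ± 0.24). At 4 h erythroid markers had a median of -2.11 (0 genes called, 0 adjusted over the list alone, adjusted p = 1.2e-05, adjusted p = 0.669 with an estimated correlation). Replicate 3 of that group held 0.283% haemoglobin counts, 704 CPM of Hbb-bs and 2.24 CPM of S100a8, genes chosen after their values were seen. In all 1426 genes rose and 466 fell at 4 h, 618 and 443 at 8 h. The 1892 calls of 4 h became 3181 with DESeq2, 835 with the compared groups alone, 634, 690 and 568 without vehicle replicates 1, 2 and 3, and 3364, 1216 and 881 without treated replicates 1, 2 and 3. The 1061 of 8 h became 2017 with DESeq2, 59 with the compared groups alone, 2401 without the libraries that stand apart, 547, 499 and 302 without vehicle replicates 1, 2 and 3, and 375, 623 and 1762 without treated replicates 1, 2 and 3.

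In A20 tumours few interferon genes were called at 4 h and nearly all at 8 h. At 15 mg/kg 5 of 57 interferon genes rose at 4 h (37 adjusted over the list alone, median 1.84, adjusted p = 6.2e-24, adjusted p = 0.940 with an estimated correlation), among them Usp18 (3.26 ± 0.83) and the transcription factor Irf7 (2.86 ± 0.72). Both were no longer called without any 1 of the vehicle libraries or without treated replicate 2 or 3. At 8 h 54 rose (57 adjusted over the list alone, median 3.25, adjusted p = 3.3e-30, adjusted p = 0.648 with an estimated correlation). Mx2 stood at 7.51 ± 1.41, Isg15 at 5.97 ± 1.22 and Irf7 up from 21.6 ± 3.36 to 453 ± 176 CPM (4.39 ± 0.78). Ifnb1 was counted at 1.64 ± 0.587 CPM at 8 h (182 counts against 2 in vehicle, adjusted p = 0.0272). This call too ended without any 1 of the vehicle libraries or without treated replicate 2 or 3. MHC class I presentation genes rose (16 of 20 higher, 19 adjusted over the list alone, median 1.23, adjusted p = 2.0e-12, adjusted p = 0.648 with an estimated correlation), including the peptide transporter Tap2 (1.18 ± 0.18) and the immunoproteasome subunit Psmb8 (0.93 ± 0.14). Gzmb (3.20 ± 0.79), the costimulatory receptor Cd40 (1.60 ± 0.18), the feedback inhibitor Socs1 (3.02 ± 0.63) and the monocyte gene Ly6c2 (2.95 ± 0.66) rose. B cell markers did not pass (median -0.08, adjusted p = 0.654), with Ms4a1 (CD20) at -1.11 ± 0.24 and Ighm at 0.77 ± 0.15. Cd274 had log2 0.70 ± 0.27 (adjusted p = 0.0706). Scand1 (3.70 ± 0.47 at 4 h) and the mitochondrial mt-Atp8 (-2.99 ± 0.32 at 8 h) stood at the ends of the ranking. These do not separate dose from identifier range. In these tumours 324 genes rose and 212 fell at 4 h, 1596 and 1802 at 8 h (1728 and 1679 with RLE size factors, 2043 and 1981 with DESeq2). The 536 calls of 4 h became 984 with DESeq2, 301 with no low-count filter, 303 with the compared groups alone, 1027 without the libraries that stand apart, 201 and 160 without vehicle replicates 2 and 3, and 142 and 138 without treated replicates 2 and 3. The 3398 of 8 h became 5971 with the compared groups alone, 2191 and 2187 without vehicle replicates 1 and 2, and 2153 without treated replicate 3.

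In B16F10 tumours no interferon gene was called at 15 mg/kg. The list had a median of 0.39 at 4 h (adjusted p = 0.102) and 0.20 at 8 h (adjusted p = 0.254), with 0 and 0 genes adjusted over the list alone. Isg15 stood at 7.20 ± 1.22 CPM against 4.54 ± 2.65 in vehicle at 8 h (0.66 ± 0.69, adjusted p = 0.621). Mx1 was at -0.25 ± 0.73 and Cxcl10 at 1.70 ± 0.55 at 4 h (adjusted p = 0.0947). The list was called at 4 h without treated replicate 2 (median 0.85), without vehicle replicate 1 (0.54) or with no low-count filter (0.39), and at 8 h without vehicle replicate 1 (0.60). What did rise at 8 h were glucocorticoid response genes (5 of 14 higher, 10 adjusted over the list alone, median 1.06, adjusted p = 0.00135, 0.960 with an estimated correlation), immediate early genes (4 of 19 higher, 10 adjusted over the list alone, median 0.63, adjusted p = 0.0260, 0.960 with an estimated correlation) and heat shock and unfolded protein response genes (4 of 24 higher, 6 adjusted over the list alone, median 0.26, adjusted p = 0.0135, 0.960 with an estimated correlation). Replicate 3 of this group stood apart, with 1.47% haemoglobin counts. Without it Jun went from 2.15 ± 0.54 to 1.02 and was not called, nor was it without vehicle replicate 1 (2.12) or 3 (2.09) or with the compared groups alone (2.20). Hba-a1 went from 4.03 ± 1.13 to -0.24 without replicate 3. Cell cycle genes had a small decrease (3 of 32 lower, 7 adjusted over the list alone, median -0.16, adjusted p = 0.0453, adjusted p = 0.960 with an estimated correlation), Ccne2 changing by -1.39 ± 0.20. Melanocyte markers did not pass (median -0.34, adjusted p = 0.102 at 4 h, -0.38, adjusted p = 0.0531 at 8 h), with 2 members lower and 5 adjusted over the list alone at 8 h. Neither did germline and early embryo genes (-0.05, adjusted p = 0.911) nor keratinocyte, muscle and fat markers (0.24, adjusted p = 0.479) at 8 h. Here 269 genes rose and 302 fell at 4 h, 415 and 789 at 8 h (481 and 602 with RLE size factors, 786 and 895 with DESeq2). The 571 calls of 4 h became 928 with DESeq2, 340 with no low-count filter, 14 with the compared groups alone, 234 and 136 without vehicle replicates 1 and 3, and 122 without treated replicate 1. The 1204 of 8 h became 763 with no low-count filter, 5 with the compared groups alone, 752 without the libraries that stand apart, 303 and 419 without vehicle replicates 1 and 3, and 752 without treated replicate 3.

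Sumo3, which encodes a SUMO protein, rose in all 12 comparisons at 15 mg/kg, from 0.57 in A20 tumours at 4 h to 1.24 in BALB/c blood at 4 h. Of the subunit genes of the targeted enzyme, Sae1 had -0.11 ± 0.13 and Uba2 -0.29 ± 0.14 in BALB/c spleen at 8 h, neither called. In BALB/c blood at 8 h Sae1 was lower (-0.68 ± 0.16), no longer called with the compared groups fitted alone. In BALB/c blood Sumo3 also differed within an identifier range, between 5 and 2.5 mg/kg at 4 h, 1 of 20 dose steps (log2 0.67, adjusted p = 0.0274).

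**Figure D4:**
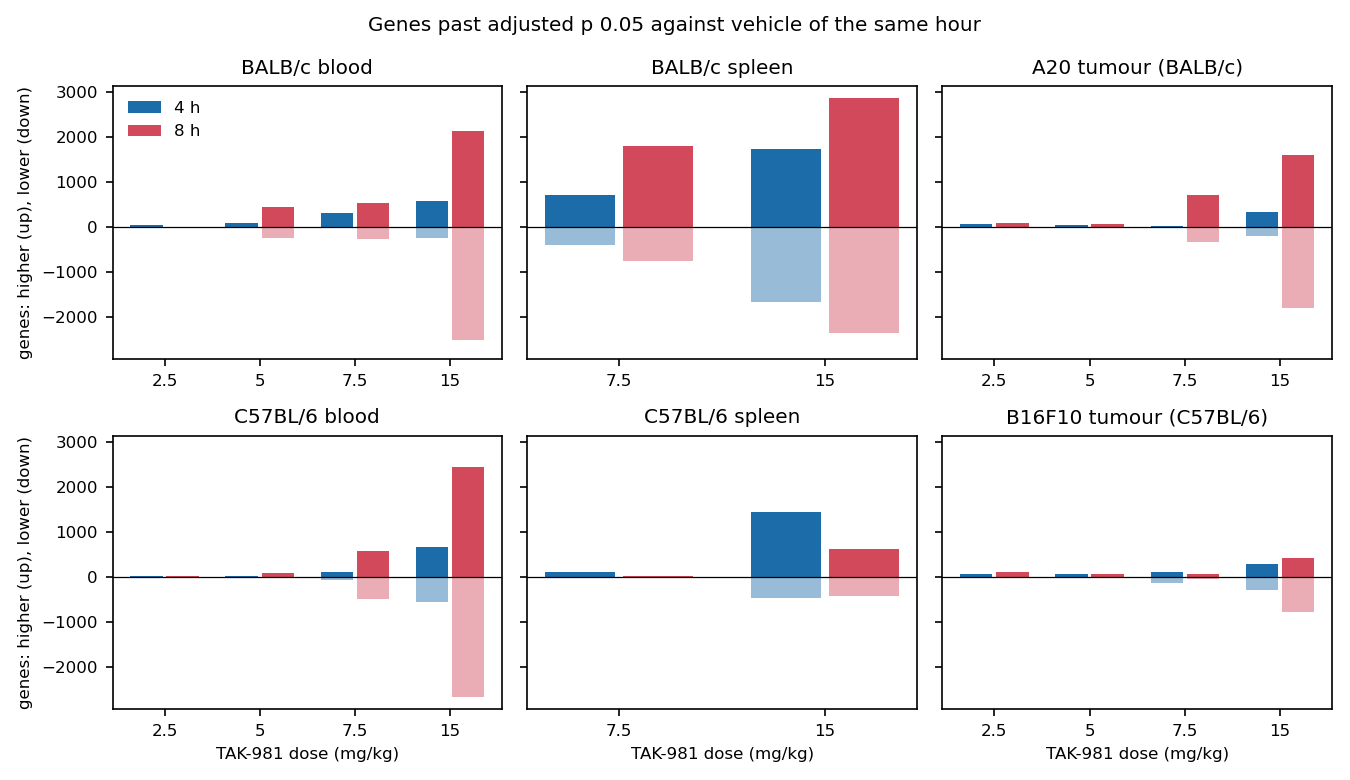
Genes with an edgeR adjusted p under 0.05 against vehicle, higher above 0 and lower below 0 (vertical axis, number of genes), by dose in mg/kg (horizontal axis) for each tissue, model and hour, 3 mice per group. BALB/c blood at 8 h goes from 0 genes at 2.5 mg/kg to 4662 at 15 mg/kg.

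Lower doses moved the interferon genes in blood, spleen and A20 tumours. In BALB/c blood the list rose at 5 mg/kg at 4 h (29 of 57 higher, 53 adjusted over the list alone, median 1.08, adjusted p = 2.4e-68) and at 7.5 mg/kg (53 of 57 higher, 55 adjusted over the list alone, median 2.35, adjusted p = 1.9e-144). At 2.5 mg/kg its median was 0.14 (adjusted p = 0.00374, 0.934 with an estimated correlation), a call that ended without treated replicate 3 (0.08). Over all genes 329 were called at 7.5, 83 at 5 and 55 at 2.5 mg/kg at 4 h, and 813, 678 and 0 at 8 h. For the count of 0 edgeR's unadjusted p was under 0.05 for 1716 genes, and DESeq2 called 239. In C57BL/6 blood 164, 9 and 10 genes were called at 4 h and 1064, 82 and 14 at 8 h, at 7.5, 5 and 2.5 mg/kg. Their interferon list rose at 5 mg/kg at 8 h (20 of 57 higher, 47 adjusted over the list alone, median 1.76, adjusted p = 7.3e-47, adjusted p = 0.113 with an estimated correlation). A20 tumours had 22, 55 and 68 calls at 4 h and 1038, 83 and 88 at 8 h. The 1038 became 39, 87 and 84 without vehicle replicates 1, 2 and 3, 2128, 4108 and 91 without treated replicates 1, 2 and 3, and 0 with the compared groups alone. Of the 40 counts against vehicle 37 moved by over 1.5 times in some fit with 1 library left out. The list was lower there at 2.5 mg/kg 4 h (0 of 57 lower, 0 adjusted over the list alone, median -0.36, adjusted p = 0.00311, 0.903 with an estimated correlation) and higher at 7.5 mg/kg 8 h (47 of 57 higher, 57 adjusted over the list alone, median 2.67, adjusted p = 2.1e-32, 0.769 with an estimated correlation). Replicate 3 of that group, with 73.2 CPM of the T-cell gene Cd3e, scored 4.46 against 2.70 and 1.24, and without it the median was 1.66. In B16F10 tumours 250, 94 and 59 were called at 4 h and 116, 61 and 116 at 8 h. Their list passed at 5 mg/kg (median 0.92, adjusted p = 5.4e-08, 0.634 with an estimated correlation) and 7.5 mg/kg at 4 h (median 0.68, adjusted p = 1.7e-05, 0.974 with an estimated correlation). It also passed at 7.5 mg/kg at 8 h (median 0.80, adjusted p = 2.4e-07, 0.999 with an estimated correlation), each time with 0 of 57 higher, 0 adjusted over the list alone. The 7.5 mg/kg calls ended without treated replicate 1 at 4 h (median 0.25) and without treated replicate 3 at 8 h (0.21). At 7.5 mg/kg BALB/c spleens had 1094 and 2548 calls at 4 h and 8 h and C57BL/6 spleens 108 and 6. The list's medians there were 2.81 and 2.20 (56 and 55 of 57 higher) and 2.09 and 1.84 (9 and 0), calls lost with an estimated correlation.

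**Figure D5:**
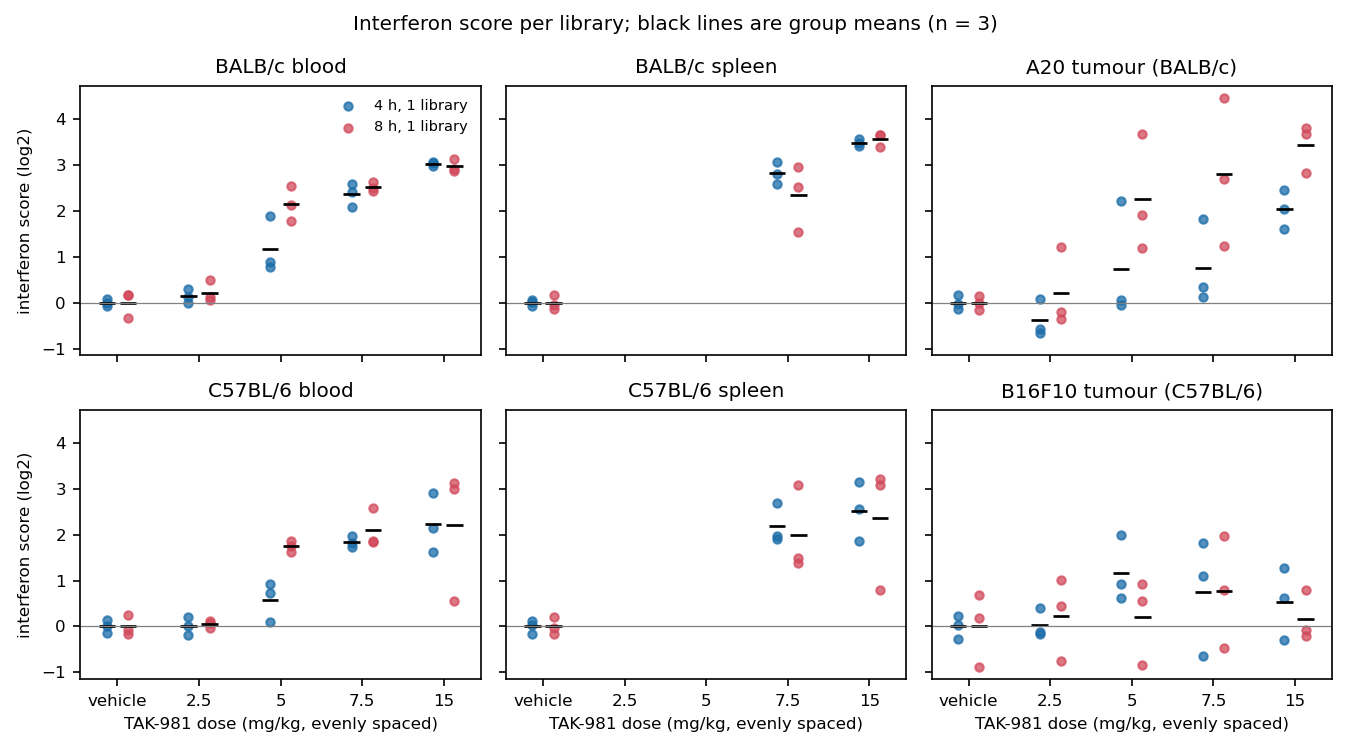
Interferon score of each library (vertical axis, mean log2 change of the list's genes from the mean of vehicle) by dose in mg/kg (horizontal axis), with points for libraries and black lines for group means of 3 mice. In BALB/c blood at 4 h the means rise from 0.14 at 2.5 to 3.03 at 15 mg/kg.

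Across the 12 treated libraries of each blood and tumour series the interferon score followed dose in blood and in A20 tumours. These were 8 relations, each tested by a two-sided permutation test. In BALB/c blood Spearman's rho was 0.972 (permutation p = 1.0e-05, adjusted 8.0e-05) and r 0.892 (permutation p = 1.0e-04, adjusted 8.0e-04) at 4 h, r being Pearson's. At 8 h they were 0.928 (permutation p = 1.1e-04, adjusted 4.4e-04) and r 0.791 (permutation p = 0.00459, adjusted 0.0122). C57BL/6 blood had a rho of 0.885 (permutation p = 3.3e-04, adjusted 8.8e-04) and r 0.844 (permutation p = 3.0e-04, adjusted 0.00120) at 4 h and 0.756 (permutation p = 0.00761, adjusted 0.0122) and r 0.601 (permutation p = 0.0393, adjusted 0.0524) at 8 h. For A20 tumours rho was 0.756 (permutation p = 0.00717, adjusted 0.0122) and r 0.745 (p = 0.00618, adjusted 0.0124) at 4 h and 0.734 (p = 0.00991, adjusted 0.0132) and r 0.666 (p = 0.0199, adjusted 0.0318) at 8 h. B16F10 tumours had a rho of 0.173 (permutation p = 0.610, adjusted 0.697) and r 0.0583 (p = 0.856, adjusted 0.935) at 4 h and 0.0216 (p = 0.972, adjusted 0.972) and r -0.0267 (p = 0.935, adjusted 0.935) at 8 h. Without the 2 libraries farthest from the median dose rho and r became 0.963 and 0.869 (4 h) and 0.887 and 0.768 (8 h) in BALB/c blood. At 4 h and 8 h they became 0.925 and 0.927 and 0.661 and 0.268 in C57BL/6 blood, 0.686 and 0.573 and 0.787 and 0.670 in A20 tumours and 0.459 and 0.372 and 0.245 and 0.253 in B16F10 tumours. All 15 mg/kg libraries tie as farthest and only 1 was kept. These values hang on which one, and cannot decide whether the relation rests on that dose. In C57BL/6 blood at 8 h rho was 0.259 with a score from log2(FPKM + 0.1). Within the lower and the higher identifier range, 6 libraries each, rho was 0.878 in both at both hours in BALB/c blood (exact p = 0.1, the smallest this size allows). It was 0.683 and 0.293 at 4 h and 0.878 and 0.293 at 8 h in C57BL/6 blood, 0.488 and 0.683 and 0.683 and 0.293 in A20 tumours and 0.878 and -0.0976 and -0.0976 and -0.0976 in B16F10 tumours (exact p 0.1 to 1). The step of 5 against 2.5 mg/kg raised the list in BALB/c blood at 8 h (51 genes called, median 1.98, adjusted p = 1.1e-64). For 15 against 7.5 mg/kg no member was called in A20 tumours at 4 h (median 1.25, adjusted p = 2.3e-30, adjusted p = 0.984 with an estimated correlation, 2 of 10 splits as large), BALB/c blood at 4 h (22 adjusted over the list alone, median 0.66, adjusted p = 3.0e-39, adjusted p = 0.0564 with an estimated correlation) or B16F10 tumours at 8 h (median -0.59, adjusted p = 8.9e-05, adjusted p = 0.821 with an estimated correlation, 0.01 without 7.5 mg/kg replicate 3). Genes called between 15 and 7.5 mg/kg at 8 h numbered 2308 in A20 tumours, 755 in BALB/c spleen, 696 in C57BL/6 blood, 242 in BALB/c blood, 2 in C57BL/6 spleen and 0 in B16F10 tumours (edgeR unadjusted p under 0.05 for 1501, DESeq2 48). With the compared groups alone the first 4 became 1, 55, 0 and 1, and with 1 library left out 677 to 3280, 299 to 1104, 75 to 1482 and 39 to 913. For the 696, 3 of the 10 splits of the 6 samples gave as many (highest 2601).

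The effect of 15 mg/kg differed between 8 h and 4 h for B-cell genes. In BALB/c blood 142 genes had a different effect, and B cell markers dropped further by 8 h (9 of 15 lower, 15 adjusted over the list alone, median -1.95, adjusted p = 2.7e-19, adjusted p = 0.207 with an estimated correlation), with Fcer2a at -4.00 ± 0.66. Neutrophil markers gained (1 of 18 higher, 9 adjusted over the list alone, median 1.14, adjusted p = 7.2e-07, adjusted p = 0.272 with an estimated correlation). Fcer2a also fell further in C57BL/6 spleen (-2.80 ± 0.32), 1 of 13 genes that differed there, and 43 differed in BALB/c spleen. The E protein gene Tcf3 fell further in C57BL/6 blood (-1.36 ± 0.22), 1 of 7 genes there, a call that ended with the compared groups alone and without any 1 of 4 libraries (vehicle 4 h replicates 2 and 3, vehicle 8 h replicate 1, treated 4 h replicate 1). A20 tumours had 0 (edgeR unadjusted p under 0.05 for 2145, DESeq2 67) and B16F10 tumours 0 (unadjusted 469, DESeq2 0). The interferon list in A20 tumours had 0 members called (median 1.42, adjusted p = 2.3e-09, adjusted p = 0.673 with an estimated correlation). The A20 count became 996 with the compared groups fitted alone. With 1 library left out C57BL/6 blood gave 0 (vehicle 4 h replicate 2 or 8 h replicate 1) to 389 (treated 8 h replicate 1). BALB/c blood gave 33 (vehicle 4 h replicate 1) to 255 (treated 8 h replicate 2).

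Between models the 15 mg/kg effect on the interferon list had a lower median in C57BL/6 mice, with few members called outside tumours at 8 h. In blood at 8 h this rested on 1 mouse. The difference, C57BL/6 minus BALB/c, had a median of -0.75 and -0.73 in blood and -1.01 and -1.09 in spleen at 4 h and 8 h (adjusted p of at most 9.9e-07, and of at least 0.615 with an estimated correlation). Members lower numbered 0 and 0 in blood, 1 and 0 in spleen (2 and 0 adjusted over the list alone) and 0 in tumours at 4 h (2), and with fry tumours at 8 h alone passed. Without C57BL/6 15 mg/kg replicate 3 it was 0.030 (adjusted p = 0.787) in blood and -0.39 (adjusted p = 4.6e-04) in spleen at 8 h. Without replicate 3 of 4 h it was -1.15 in blood, and without replicate 2 of 4 h -0.43 in blood and -0.64 in spleen. Without 8 h replicate 1 or 2 blood had -1.24 and -1.25. In tumours the difference was -1.24 (adjusted p = 1.6e-19, 0.701 with an estimated correlation) and -3.00 (13 genes lower at 8 h, 50 adjusted over the list alone, adjusted p = 9.3e-38, 0.206 with an estimated correlation). Mx1 differed by -6.84 ± 1.58, a call that ended in 7 of the 12 fits with 1 library left out. In blood at 8 h platelet and megakaryocyte markers were higher (2 of 12 higher, 8 adjusted over the list alone, median 1.10, adjusted p = 1.7e-06, 0.805 with an estimated correlation). Genes with a different effect numbered 2 and 88 in blood, 395 and 3 in spleen, 4 and 120 in tumour. The blood count of 88 became 9 to 916 with 1 library left out and 0 with the compared groups alone. The tumour count of 120 became 17 to 140 with 1 library left out and 308 without the libraries that stand apart. The spleen count of 395 ranged from 69 (without C57BL/6 vehicle replicate 1) to 2189 (without C57BL/6 15 mg/kg replicate 1). In spleen at 4 h erythroid (-2.54, 0 called), neutrophil (-2.05) and cell cycle genes (-1.53) also had lower and T cell markers (1.22) higher medians, adjusted p of at most 0.00116, lost with an estimated correlation. C57BL/6 15 mg/kg replicate 3 held 0.283% haemoglobin there (set median 7.85%), so these may rest on it. Strain and tumour line differ together in this design.

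Between tissues the list's rise was larger in BALB/c spleen than blood at 4 h (median difference 0.45, adjusted p = 0.0317). That call ended without blood vehicle replicate 1 (0.39), blood 15 mg/kg replicate 1 or 3 (both 0.42) or spleen vehicle replicate 3 (0.41). The rise was smaller in the tumour than in blood at 4 h in BALB/c (-1.14, adjusted p = 3.9e-14) and at 4 h and 8 h in C57BL/6 mice (-1.77, adjusted p = 2.4e-13, and -1.76, adjusted p = 1.2e-11). With an estimated correlation the lowest adjusted p of the 8 differences was 0.682. The others were 0.58 (BALB/c spleen, 8 h, adjusted p = 0.0512, 0.0209 with the mouse as a block), 0.27 (A20 tumour, 8 h, mean 0.40, test Down, adjusted p = 0.988), 0.48 (C57BL/6 spleen, 4 h, adjusted p = 0.463) and 0.28 (8 h, mean 0.21, test Down, adjusted p = 0.891).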

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

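All tests of the 3 patterns weighed below were chosen after the result was seen, except the level of the interferon genes in B16F10 tumours. The splits of the samples were planned.

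The following effects of 15 mg/kg differed by a test of the difference between groups. Between 8 h and 4 h the effect differed for 142 genes in BALB/c blood, 43 in BALB/c spleen, 7 in C57BL/6 blood and 13 in C57BL/6 spleen. Between models it differed for 2 and 88 genes in blood, 395 and 3 in spleen and 4 and 120 in tumour at 4 h and 8 h. For the interferon list the median difference from blood was 0.45 in BALB/c spleen at 4 h, -1.14 in A20 tumours at 4 h, and -1.77 and -1.76 in B16F10 tumours at 4 h and 8 h. All were lost with an estimated correlation (lowest adjusted p = 0.682) and with fry, and the 0.45 without any 1 of 4 libraries.

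Relabelling the samples could not decide whether a difference is due to chance, because it moves part of the treatment effect into the difference. Among 100 drawn from the 200 relabellings, the real one included, 20 gave as many genes over time in BALB/c blood (highest other 4506), 11 in BALB/c spleen (6533), 18 in C57BL/6 blood (6279) and 9 in C57BL/6 spleen (3696). In A20 and B16F10 tumours, where edgeR called 0 genes over time (unadjusted p under 0.05 for 2145 and 469, DESeq2 67 and 0), all 100 did (3420 and 2645). Between models 19 and 55 did in blood at 4 h and 8 h (2494 and 7601), 16 and 18 in spleen (4628 and 6012) and 13 and 16 in tumour (1524 and 3881). For the list, 72 and 74 relabellings gave a median difference as large in BALB/c spleen at 4 h and 8 h (6.41 and 6.77), and 65 and 84 in A20 tumours (4.75 and 6.43). In C57BL/6 mice 84 and 86 did in spleen (4.45 and 4.44) and 16 and 24 in tumours (2.91 and 3.25). Those that called many times the real count point to a structure of the samples, namely the treatment itself.

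Replicate 3 of C57BL/6 mice at 15 mg/kg 8 h had 0.0636, 0.987 and 0.115 CPM of Xist in blood, spleen and tumour, with an interferon score of 0.546 in blood and 0.802 in spleen, against 2.99 or more and 3.08 or more in the other 2 mice. A male mouse was argued against by 0 counts of 4 Y-linked genes in all 3 libraries. A vehicle mouse under the wrong label was argued against in spleen, where the score lay 0.604 above the highest vehicle library (vehicle range 0.361). In blood it lay 0.304 above (range 0.411), so this cannot be told apart there. A missing X chromosome stays open, because 5 genes that escape X inactivation had tissue medians of up to 0.178 (-0.388 in blood and -0.345 in spleen), and 23 of 153 other libraries also lay below -0.2.

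Liver transcripts ranged widely between blood libraries. TAK-981 as the whole cause was argued against by vehicle libraries of 1 strain whose Alb differed 1474 times. Over 60 blood libraries 17 liver markers followed Alb with a median correlation of 0.985 (lowest 0.859), as liver RNA in the blood sample would give. Whether it entered at collection or from damaged liver in the animal stays open and was not tested.

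The interferon list was called in A20 tumours at 15 mg/kg and not in B16F10 tumours, with a tested difference of -1.24 and -3.00 at 4 h and 8 h. With an estimated correlation these calls were lost (adjusted p = 0.940 and 0.648 in A20 tumours, 0.701 and 0.206 for the difference). Fewer reads in B16F10 libraries were argued against by a ratio of median counts of 1.18 (B16F10 to A20). The list was measurable there, at a median of 5.46 CPM in vehicle (A20 8.78). The ratio of SDs of the score was 0.926 over all groups but 1.79 over vehicle and 15 mg/kg, so a wider spread in B16F10 tumours cannot be told apart. A difference between the tumour lines or the strains may remain, and the 2 were not tested apart.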

How the results depend on the processing

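The alternatives without the libraries that stand apart, with log2 Alb CPM as a covariate, the gene counts of the dose steps, and all alternatives of the interferon list's time and model differences were chosen after seeing the data. All others were planned, as were the splits of the samples. Doses are in mg/kg against vehicle unless another dose is named, 15/7.5 and 5/2.5 stand for the direct steps between these doses, "by time" for the effect at 8 h minus that at 4 h, and brackets hold the reported value. Where fewer samples or an estimated correlation do not explain a change, the cause was not tested. Where a list's value equals the reported one, its call changed. A count is taken as changed when it moves by over 1.5 times.

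DESeq2 in place of edgeR gave more genes in most comparisons, and 32 of 40 counts against vehicle changed. BALB/c blood gave 677 (55) at 2.5, 188 (83) at 5, 509 (329) at 7.5, 33 (0) at 15/7.5 and 682 (70) at 5/2.5 at 4 h, and 239 (0) at 2.5, 1897 (678) at 5, 1477 (813) at 7.5, 598 (242) at 15/7.5 and 2158 (1071) at 5/2.5 at 8 h, and 461 (142) by time. BALB/c spleen gave 1709 (1094) at 7.5 and 170 (0) at 15/7.5 at 4 h, and 1371 (755) at 15/7.5 at 8 h, and 480 (43) by time. A20 tumour gave 168 (68) at 2.5, 129 (55) at 5, 144 (22) at 7.5, 984 (536) at 15, 3 (0) at 15/7.5 and 4 (0) at 5/2.5 at 4 h, and 206 (88) at 2.5, 598 (83) at 5, 2178 (1038) at 7.5 and 8 (0) at 5/2.5 at 8 h, and 67 (0) by time. C57BL/6 blood gave 162 (10) at 2.5, 254 (9) at 5, 894 (164) at 7.5, 2261 (1241) at 15, 63 (1) at 15/7.5 and 10 (1) at 5/2.5 at 4 h, and 65 (14) at 2.5, 360 (82) at 5, 1817 (1064) at 7.5, 1303 (696) at 15/7.5 and 203 (5) at 5/2.5 at 8 h, and 210 (7) by time. C57BL/6 spleen gave 473 (108) at 7.5, 3181 (1892) at 15 and 107 (0) at 15/7.5 at 4 h, and 242 (6) at 7.5, 2017 (1061) at 15 and 104 (2) at 15/7.5 at 8 h, and 302 (13) by time. B16F10 tumour gave 170 (59) at 2.5, 349 (94) at 5, 538 (250) at 7.5, 928 (571) at 15, 4 (0) at 15/7.5 and 6 (0) at 5/2.5 at 4 h, and 462 (116) at 2.5, 169 (61) at 5, 451 (116) at 7.5, 48 (0) at 15/7.5 and 2 (0) at 5/2.5 at 8 h. Model differences gave 217 (2) in blood, 1031 (395) in spleen and 23 (4) in tumour at 4 h, and 485 (88) in blood, 27 (3) in spleen and 353 (120) in tumour at 8 h.

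With the compared groups fitted alone, and so with fewer samples to estimate the spread, 34 of 40 counts against vehicle changed. BALB/c blood gave 0 (55) at 2.5, 4 (83) at 5, 554 (329) at 7.5 and 0 (70) at 5/2.5 at 4 h, and 12 (0) at 2.5, 108 (678) at 5, 450 (813) at 7.5, 1738 (4662) at 15 and 1 (242) at 15/7.5 at 8 h, and 26 (142) by time. BALB/c spleen gave 183 (0) at 15/7.5 at 4 h, and 60 (2548) at 7.5 and 55 (755) at 15/7.5 at 8 h, and 173 (43) by time. A20 tumour gave 19 (68) at 2.5, 0 (55) at 5, 1 (22) at 7.5 and 303 (536) at 15 at 4 h, and 6 (88) at 2.5, 2 (83) at 5, 0 (1038) at 7.5, 5971 (3398) at 15 and 1 (2308) at 15/7.5 at 8 h, and 996 (0) by time. C57BL/6 blood gave 16 (10) at 2.5, 2954 (1241) at 15, 0 (1) at 15/7.5 and 0 (1) at 5/2.5 at 4 h, and 89 (14) at 2.5, 1161 (82) at 5, 130 (1064) at 7.5, 327 (5104) at 15, 0 (696) at 15/7.5 and 1713 (5) at 5/2.5 at 8 h. C57BL/6 spleen gave 963 (108) at 7.5 and 835 (1892) at 15 at 4 h, and 1 (6) at 7.5, 59 (1061) at 15 and 0 (2) at 15/7.5 at 8 h, and 1 (13) by time. B16F10 tumour gave 14 (59) at 2.5, 0 (94) at 5, 0 (250) at 7.5 and 14 (571) at 15 at 4 h, and 6 (116) at 2.5, 39 (61) at 5, 0 (116) at 7.5 and 5 (1204) at 15 at 8 h. Model differences gave 1 (2) in blood, 211 (395) in spleen and 9 (4) in tumour at 4 h, and 0 (88) in blood at 8 h.

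Without the libraries that stand apart, counts changed as follows. A20 tumour held 67 (22) at 7.5 and 1027 (536) at 15 at 4 h, and 314 (83) at 5 and 91 (1038) at 7.5 at 8 h. C57BL/6 blood held 23 (9) at 5, 617 (164) at 7.5, 2479 (1241) at 15 and 2 (1) at 5/2.5 at 4 h, and 299 (82) at 5, 2177 (1064) at 7.5 and 138 (5) at 5/2.5 at 8 h, and 3 (7) by time. C57BL/6 spleen held 527 (108) at 7.5 at 4 h, and 202 (6) at 7.5 and 2401 (1061) at 15 at 8 h. B16F10 tumour held 174 (94) at 5 and 385 (250) at 7.5 at 4 h, and 175 (116) at 2.5, 192 (116) at 7.5 and 752 (1204) at 15 at 8 h. Model differences held 23 (2) in blood and 8 (4) in tumour at 4 h, and 916 (88) in blood and 308 (120) in tumour at 8 h. With no low-count filter, and so with more genes tested, 27 of 40 counts against vehicle stayed within 1.5 times. BALB/c blood held 121 (242) at 15/7.5 at 8 h. A20 tumour held 35 (55) at 5, 7 (22) at 7.5 and 301 (536) at 15 at 4 h, and 587 (1038) at 7.5 and 1429 (2308) at 15/7.5 at 8 h. C57BL/6 blood held 769 (1241) at 15 at 4 h, and 647 (1064) at 7.5 at 8 h. C57BL/6 spleen held 14 (6) at 7.5 and 4 (2) at 15/7.5 at 8 h. B16F10 tumour held 55 (94) at 5, 100 (250) at 7.5 and 340 (571) at 15 at 4 h, and 70 (116) at 2.5, 64 (116) at 7.5 and 763 (1204) at 15 at 8 h. Model differences held 4 (2) in blood and 2 (4) in tumour at 4 h, and 41 (88) in blood at 8 h.

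The amount of liver RNA, entered as log2 Alb CPM in blood, moved some counts up and others down. BALB/c blood reached 89 (55) at 2.5 and 228 (70) at 5/2.5 at 4 h, and 17 (0) at 2.5, 325 (678) at 5, 2275 (4662) at 15 and 158 (1071) at 5/2.5 at 8 h, and 40 (142) by time. C57BL/6 blood reached 15 (9) at 5 and 2 (1) at 5/2.5 at 4 h, and 271 (696) at 15/7.5 and 27 (5) at 5/2.5 at 8 h, and 90 (7) by time. Model differences reached 0 (2) in blood at 4 h, and 133 (88) in blood at 8 h. With RLE size factors all 40 counts against vehicle stayed within 1.5 times. BALB/c blood reached 160 (242) at 15/7.5 at 8 h. C57BL/6 spleen reached 4 (2) at 15/7.5 at 8 h. Without haemoglobin and immunoglobulin genes 38 of 40 did. A20 tumour came to 9 (22) at 7.5 at 4 h. C57BL/6 spleen came to 70 (108) at 7.5 at 4 h. RLE moved the median of all genes against TMM by 0.103 in BALB/c blood and 0.126 in C57BL/6 blood at 15 mg/kg 8 h, and by 0.102 for the time difference of C57BL/6 blood.

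Between the groups of a set replicate numbers do not pair libraries. The mean correlation of libraries of 1 number ran from -0.029 to 0.042 there, and the numbers were still fitted as a block. BALB/c blood came to 658 (1071) at 5/2.5 at 8 h. BALB/c spleen came to 26 (43) by time. A20 tumour came to 9 (22) at 7.5 at 4 h, and 445 (1038) at 7.5 at 8 h. C57BL/6 blood came to 108 (164) at 7.5 and 2 (1) at 15/7.5 at 4 h, and 3 (5) at 5/2.5 at 8 h. C57BL/6 spleen came to 1 (2) at 15/7.5 at 8 h, and 6 (13) by time. Across tissues the correlation of blood with spleen of 1 number was 0.0786 and 0.127 in BALB/c and C57BL/6 mice, against -0.0387 and -0.0575 for other numbers. For tumours it was -0.0143 and -0.0184. Replicate 3 of C57BL/6 mice at 15 mg/kg 8 h lacked Xist in all 3 tissues. The numbers may thus name the mouse across tissues, which the reported tissue differences do not use. A block for the mouse brought the call of 1 of 8 (adjusted p = 0.0209). Tissue differences had 0.58 (0.58) for BALB/c spleen at 8 h.

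With 1 library left out, and so with fewer samples, the counts ran over these ranges. BALB/c blood showed 10 to 340 at 2.5, 18 to 109 at 5, 520 to 699 at 15, 0 to 1 at 15/7.5 and 0 to 619 at 5/2.5 at 4 h, and 0 to 76 at 2.5, 312 to 1045 at 5, 537 to 743 at 7.5, 2774 to 4945 at 15, 39 to 913 at 15/7.5 and 175 to 1948 at 5/2.5 at 8 h, and 33 to 255 by time. BALB/c spleen showed 614 to 849 at 7.5 and 2231 to 3103 at 15 at 4 h, and 652 to 4172 at 7.5 and 299 to 1104 at 15/7.5 at 8 h, and 3 to 69 by time. A20 tumour showed 11 to 69 at 2.5, 13 to 34 at 5, 0 to 9 at 7.5 and 138 to 748 at 15 at 4 h, and 36 to 77 at 2.5, 34 to 251 at 5, 39 to 4108 at 7.5, 2153 to 2633 at 15, 677 to 3280 at 15/7.5 and 0 to 1 at 5/2.5 at 8 h, and 0 to 3 by time. C57BL/6 blood showed 0 to 7 at 2.5, 12 to 283 at 7.5, 293 to 1004 at 15, 0 to 8 at 15/7.5 and 0 to 1 at 5/2.5 at 4 h, and 4 to 8 at 2.5, 7 to 39 at 5, 75 to 2048 at 7.5, 3290 to 5115 at 15, 75 to 1482 at 15/7.5 and 0 to 5 at 5/2.5 at 8 h, and 0 to 389 by time. C57BL/6 spleen showed 21 to 47 at 7.5, 568 to 3364 at 15 and 0 to 2 at 15/7.5 at 4 h, and 1 to 27 at 7.5, 302 to 1762 at 15 and 1 to 18 at 15/7.5 at 8 h, and 4 to 91 by time. B16F10 tumour showed 26 to 79 at 2.5, 29 to 68 at 5, 11 to 441 at 7.5, 122 to 559 at 15, 0 to 1 at 15/7.5 and 0 to 2 at 5/2.5 at 4 h, and 38 to 205 at 2.5, 22 to 37 at 5, 7 to 280 at 7.5, 303 to 1112 at 15 and 0 to 2 at 15/7.5 at 8 h, and 0 to 1 by time. Model differences showed 0 to 36 in blood, 69 to 2189 in spleen and 0 to 2 in tumour at 4 h, and 9 to 916 in blood and 17 to 140 in tumour at 8 h.

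Against vehicle 185 of 192 fits with 1 library left out kept a call of the interferon list, and 6 of 48 gained one. The medians of the results with a change ran as follows. BALB/c blood had 0.071 to 0.20 at 2.5 at 4 h, and 0.079 to 0.33 at 2.5 at 8 h, and -0.30 to 0.0073 by time. A20 tumour had -0.050 to 1.07 at 5 and 0.18 to 0.88 at 7.5 at 4 h, and -0.15 to 1.43 at 15/7.5 at 8 h. C57BL/6 blood had 0.076 to 0.73 at 15/7.5 at 4 h, and -0.29 to 0.98 at 15/7.5 at 8 h, and -0.51 to 0.78 by time. C57BL/6 spleen had 0.067 to 0.70 at 15/7.5 at 4 h, and -0.024 to 1.12 at 15/7.5 at 8 h, and -0.61 to 0.57 by time. B16F10 tumour had 0.25 to 1.54 at 7.5, 0.12 to 0.85 at 15 and -0.91 to 0.19 at 15/7.5 at 4 h, and -0.17 to 0.65 at 2.5, -0.19 to 0.59 at 5, 0.21 to 1.51 at 7.5, -0.12 to 0.60 at 15, -1.18 to 0.0092 at 15/7.5 and -0.39 to 0.43 at 5/2.5 at 8 h, and -0.54 to 0.15 by time. Model differences had -1.25 to 0.030 in blood at 8 h. Tissue differences had 0.38 to 0.49 for BALB/c spleen at 4 h, and 0.39 to 0.80 for BALB/c spleen and -0.61 to 1.06 for C57BL/6 spleen at 8 h. B16F10 tumours at 15/7.5 had 0.08 without 15 mg/kg replicate 2 and 0.19 without 7.5 mg/kg replicate 1 at 4 h. At 5/2.5 8 h they had 0.27 without 2.5 mg/kg replicate 1. Direction also changed in A20 tumours at 5 mg/kg 4 h without treated replicate 2 and at 15/7.5 8 h without 7.5 mg/kg replicate 2, in C57BL/6 spleen at 15/7.5 8 h without 15 mg/kg replicate 1, and for spleen minus blood at 8 h without blood 15 mg/kg replicate 3.

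Of the 32 comparisons with vehicle that called the interferon list, 6 kept the call with an estimated correlation and 19 with the rotation test fry, and of the 6 model differences 0 and 1. The first loss follows from its construction, since correlated members widen the test. The medians are those reported, and brackets hold the adjusted p with the estimated correlation, then that of fry where it ended the call too. BALB/c blood stood at 0.14 (0.934, 0.812) at 2.5, 0.66 (0.0564, 0.0768) at 15/7.5 and 1.01 (0.540) at 5/2.5 at 4 h, and 0.22 (0.861, 0.806) at 2.5 and 0.46 (0.466, 0.252) at 15/7.5 at 8 h. BALB/c spleen stood at 2.81 (0.0510) at 7.5, 3.40 (0.112) at 15 and 0.66 (0.369, 0.181) at 15/7.5 at 4 h, and 2.20 (0.318) at 7.5, 3.28 (0.118) at 15 and 1.21 (0.122) at 15/7.5 at 8 h. A20 tumour stood at -0.36 (0.903, 0.916) at 2.5, 0.63 (0.900, 0.930) at 5, 0.55 (0.873, 0.896) at 7.5, 1.84 (0.940, 0.330) at 15, 1.25 (0.984, 0.980) at 15/7.5 and 1.06 (0.741, 0.991) at 5/2.5 at 4 h, and 2.18 (0.799, 0.232) at 5, 2.67 (0.769) at 7.5, 3.25 (0.648) at 15, 0.58 (0.941, 0.586) at 15/7.5 and 2.12 (0.530, 0.338) at 5/2.5 at 8 h, and 1.42 (0.673, 0.564) by time. C57BL/6 blood stood at 0.49 (0.542, 0.531) at 5, 1.86 (0.335) at 7.5, 2.16 (0.274) at 15, 0.41 (0.660, 0.544) at 15/7.5 and 0.51 (0.773, 0.953) at 5/2.5 at 4 h, and 1.76 (0.113) at 5, 2.05 (0.287) at 7.5, 2.16 (0.263) at 15 and 1.68 (0.151) at 5/2.5 at 8 h. C57BL/6 spleen stood at 2.09 (0.622, 0.102) at 7.5, 2.40 (0.669) at 15 and 0.38 (0.846, 0.821) at 15/7.5 at 4 h, and 1.84 (0.578, 0.20) at 7.5, 2.28 (0.284) at 15 and 0.38 (0.678, 0.933) at 15/7.5 at 8 h. B16F10 tumour stood at 0.92 (0.634, 0.350) at 5, 0.68 (0.974, 0.952) at 7.5, -0.24 (0.762, 0.854) at 15/7.5 and 0.97 (0.309, 0.312) at 5/2.5 at 4 h, and 0.80 (0.999, 0.996) at 7.5 and -0.59 (0.821, 0.781) at 15/7.5 at 8 h. Model differences stood at -0.75 (0.615, 0.542) in blood, -1.01 (0.703, 0.234) in spleen and -1.24 (0.701, 0.992) in tumour at 4 h, and -0.73 (0.805, 0.624) in blood, -1.09 (0.890, 0.755) in spleen and -3.00 (0.206) in tumour at 8 h. Tissue differences stood at 0.45 (0.903, 0.901) for BALB/c spleen, -1.14 (0.682, 0.236) for A20 tumour and -1.77 (0.972, 0.292) for B16F10 tumour at 4 h, and -1.76 (0.839, 0.0978) for B16F10 tumour at 8 h.

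With log2(FPKM + 0.1), BALB/c blood had -0.18 (0.14) at 2.5 at 4 h. B16F10 tumour had -0.32 (-0.24) at 15/7.5 at 4 h. Tissue differences had 1.01 (0.58) for BALB/c spleen at 8 h. With no low-count filter, B16F10 tumour had 0.39 (0.39) at 15 and -0.24 (-0.24) at 15/7.5 at 4 h. Tissue differences had 0.75 (0.58) for BALB/c spleen at 8 h. Without the libraries that stand apart, C57BL/6 blood had 0.98 (0.15) at 15/7.5 at 8 h, and 0.78 (-0.061) by time. C57BL/6 spleen had 0.067 (0.38) at 15/7.5 at 4 h, and 0.92 (-0.20) by time. Model differences had 0.030 (-0.73) in blood at 8 h. Tissue differences had 0.58 (0.58) for BALB/c spleen at 8 h. With log2 Alb CPM as a covariate, C57BL/6 blood had 0.27 (-0.033) at 2.5 at 4 h, and 0.43 (0.15) at 15/7.5 at 8 h. With RLE size factors, B16F10 tumour had -0.25 (-0.24) at 15/7.5 at 4 h. A prior count of 0.5 and the replicate block changed none of the 40 results against vehicle. The score of C57BL/6 blood at 8 h had a rho of 0.259 with log2(FPKM + 0.1) (0.756), which no longer passed. The other 5 relations with a call kept it there, and all 6 did with the vehicle at dose 0, a prior count of 0.5, log2 of the dose, the replicate block and without each library.

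Of the values of genes followed under the naming rule, 7 of 459 gained a call with DESeq2. Calls or directions changed for 3 of 462 with RLE size factors, 22 of 462 with no low-count filter and 17 of 462 with the block. With the compared groups alone 117 of 449 changed, 109 of them losing the call. With 1 library left out 573 of 2928 values changed, 568 losing the call. Hba-a1 in B16F10 tumours at 8 h became -0.24 without 15 mg/kg replicate 3, alone or with the other libraries that stand apart, and ran up to 4.60 without 15 mg/kg replicate 2.

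Splits of 3 against 3 libraries number 10, so their share is never under 0.1. Against vehicle the real split alone gave as many genes as the reported count (1 of 10) in 39 of 40 comparisons. The highest of the other splits, in brackets, was 0 in the comparisons not named here. BALB/c blood counted 55 (1) at 2.5 and 83 (1) at 5 at 4 h, and 4662 (2) at 15 at 8 h. BALB/c spleen counted 1094 (22) at 7.5 at 4 h, and 2548 (1175) at 7.5 at 8 h. A20 tumour counted 88 (1) at 2.5 at 8 h. C57BL/6 blood counted 5104 (1106) at 15 at 8 h. B16F10 tumour counted 94 (1) at 5 at 4 h, and 1204 (230) at 15 at 8 h. All 10 gave 0 in BALB/c blood at 2.5 mg/kg 8 h. For dose steps the real split alone was as large in 6, where the others gave 0 except for up to 441 in A20 tumours at 8 h (15/7.5, 2308). In 6 steps all 10 gave 0. Elsewhere the bracket adds how many of the 10 gave as many. BALB/c spleen counted 0 (1, 10) at 15/7.5 at 4 h. A20 tumour counted 0 (1, 10) at 15/7.5 at 4 h. C57BL/6 blood counted 1 (5, 3) at 15/7.5 and 1 (1, 2) at 5/2.5 at 4 h, and 696 (2601, 3) at 15/7.5 at 8 h. C57BL/6 spleen counted 2 (935, 2) at 15/7.5 at 8 h. B16F10 tumour counted 0 (11, 10) at 5/2.5 at 4 h, and 0 (3, 10) at 15/7.5 at 8 h. In C57BL/6 blood and spleen at 8 h other splits called several times the real count, which points to a structure of the samples.

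The size of the interferon list's median, sign aside, was compared in the same way. The real split alone was as large (1 of 10) in 24 comparisons with vehicle and 9 dose steps. BALB/c blood gave medians of 1.08 (0.66) at 5, 2.35 (1.00) at 7.5, 2.93 (1.06) at 15, 0.66 (0.40) at 15/7.5 and 1.01 (0.70) at 5/2.5 at 4 h, and 2.15 (1.07) at 5, 2.58 (1.04) at 7.5, 2.88 (1.22) at 15, 0.46 (0.26) at 15/7.5 and 1.98 (1.12) at 5/2.5 at 8 h. BALB/c spleen gave medians of 2.81 (1.08) at 7.5, 3.40 (1.21) at 15 and 0.66 (0.44) at 15/7.5 at 4 h, and 2.20 (1.33) at 7.5, 3.28 (1.38) at 15 and 1.21 (0.93) at 15/7.5 at 8 h. A20 tumour gave medians of 1.84 (1.03) at 15 at 4 h, and 2.18 (1.46) at 5, 2.67 (2.05) at 7.5, 3.25 (1.504) at 15 and 2.12 (2.02) at 5/2.5 at 8 h. C57BL/6 blood gave medians of 1.86 (0.70) at 7.5 and 2.16 (1.15) at 15 at 4 h, and 1.76 (0.81) at 5, 2.05 (1.01) at 7.5, 2.16 (2.00) at 15 and 1.68 (0.68) at 5/2.5 at 8 h. C57BL/6 spleen gave medians of 2.09 (0.99) at 7.5 and 2.40 (1.37) at 15 at 4 h, and 1.84 (1.18) at 7.5 and 2.28 (1.90) at 15 at 8 h. B16F10 tumour gave medians of 0.92 (0.87) at 5 and 0.97 (0.95) at 5/2.5 at 4 h. In the others the bracket adds the number of the 10 splits. BALB/c blood gave medians of 0.14 (0.19, 3) at 2.5 at 4 h, and 0.22 (0.35, 5) at 2.5 at 8 h. A20 tumour gave medians of 0.36 (0.47, 3) at 2.5, 0.63 (1.00, 6) at 5, 0.55 (0.84, 5) at 7.5, 1.25 (1.49, 2) at 15/7.5 and 1.06 (1.15, 3) at 5/2.5 at 4 h, and 0.19 (0.71, 9) at 2.5 and 0.58 (1.69, 7) at 15/7.5 at 8 h. C57BL/6 blood gave medians of 0.033 (0.22, 8) at 2.5, 0.49 (0.52, 3) at 5, 0.41 (0.63, 4) at 15/7.5 and 0.51 (0.58, 2) at 5/2.5 at 4 h, and 0.056 (0.22, 6) at 2.5 and 0.15 (1.59, 9) at 15/7.5 at 8 h. C57BL/6 spleen gave medians of 0.38 (0.88, 7) at 15/7.5 at 4 h, and 0.38 (1.86, 9) at 15/7.5 at 8 h. B16F10 tumour gave medians of 0.037 (0.32, 9) at 2.5, 0.68 (1.45, 4) at 7.5, 0.39 (0.95, 5) at 15 and 0.24 (1.59, 8) at 15/7.5 at 4 h, and 0.19 (1.01, 7) at 2.5, 0.18 (1.16, 7) at 5, 0.80 (1.48, 4) at 7.5, 0.20 (0.75, 9) at 15, 0.59 (1.09, 6) at 15/7.5 and 0.016 (1.07, 9) at 5/2.5 at 8 h.

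The interferon list's median, mean and test differed in sign in 7 comparisons, in none of which the test passed. These were C57BL/6 blood and B16F10 tumours at 2.5 mg/kg 4 h, BALB/c spleen and C57BL/6 blood by time, B16F10 tumours at 5/2.5 8 h, and the tissue differences at 8 h of A20 tumours and C57BL/6 spleen.

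Depth limited these results less than the spread between mice. In simulated data a log2 change of 2 was called for 42.4 to 81.8% of genes with the fitted dispersions, and for 89.4 to 98.5% with the dispersion divided by 10.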

Other observations

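The hypothesis on identifier ranges and both of its tests were chosen after the result was seen.

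Monocyte and macrophage markers rose in BALB/c blood at 15 mg/kg 8 h (1 of 18 higher, 1 adjusted over the list alone, median 1.37, adjusted p = 0.00144, 0.303 with an estimated correlation). NK cell markers (5 of 13 higher, 5 adjusted over the list alone, median 0.64, adjusted p = 0.00215, 0.324 with an estimated correlation) and costimulation genes (7 of 16 higher, 7 adjusted over the list alone, median 0.61, adjusted p = 0.00380, 0.197 with an estimated correlation) rose as well. In C57BL/6 spleen at 8 h fibroblast markers rose (2 of 12 higher, 4 adjusted over the list alone, median 0.51, adjusted p = 0.00748, 0.309 with an estimated correlation).

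Some libraries stood apart within their group. A20 tumour replicate 3 at 7.5 mg/kg 8 h had 717 CPM of Xist. Haemoglobin reached 70.4% of the counts of a C57BL/6 blood library.

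The ranges of library identifiers carry a signal of their own. The share of counts from Gm42418, which overlaps ribosomal RNA, had medians of 0.428% in vehicle, 2.29% at 7.5 and 15 mg/kg and 3.16% at 2.5 and 5 mg/kg in BALB/c blood, and 0.467%, 1.74% and 3.50% in C57BL/6 blood. Tumours had 0.133%, 0.187% and 0.515% (A20) and 0.173%, 0.265% and 0.899% (B16F10). At 2.5 mg/kg 4 h 22 genes were called in both A20 and B16F10 tumours, all in the same direction, against 0.239 expected by independent calls among 15780 genes. A change that grows with dose was argued against, because the median 15 minus 2.5 mg/kg change of these genes at 8 h was -0.46 in A20 and -0.50 in B16F10 tumours. A difference between the ranges may be the cause, since 20 of the 22 were called the same way in both tumours at 2.5 mg/kg 8 h as well. It cannot be told apart from a drug effect of the same size at every dose, because no vehicle library shares a range with a treated one.

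Shared calls of the 2 tumours were more than expected at each dose. At 2.5 mg/kg 8 h 34 were shared (0.614 expected), at 5 mg/kg 24 (0.315) and 17 (0.30), at 7.5 mg/kg 10 (0.316) and 47 (7.06) and at 15 mg/kg 179 (18) and 674 (244), each pair at 4 h and 8 h.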
